A study of Homo sapiens with 23 samples.

How the data were processed

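The series holds 23 RNA-seq libraries in 8 groups, made to ask how vesicles of melanoma cells act on neighbouring benign cells and what part PRAME plays. A375 is an established human melanoma line, and PRAME is a cancer-testis antigen, a gene normally silent in adult tissues other than testis and often expressed in melanoma. Per the labels, A375 cells were of a PRAME +/+ or a PRAME +/- genotype, with 3 libraries each and no treatment. The genotype field of these labels begins with WT for both genotypes, and whether that is a copying slip is not given in the sources used here, so PRAME +/- rests on the rest of the field and on the titles. The other 17 libraries come from recipient cells labelled as primary epidermal melanocytes, primary dermal fibroblasts or primary dermal microvascular endothelial cells, which received the vesicle preparation of PRAME +/+ or PRAME +/- A375 cells. Each recipient group had 3 libraries, except the endothelial-labelled group given PRAME +/- vesicles, which had 2. No library of recipient cells without vesicles was analysed here, so every recipient comparison is between the vesicle preparations of the 2 donor genotypes, called vesicles below. Per the labels' protocols, donor cells spent 72 h in serum-free medium, which was spun to clear debris and concentrated on filters of 100 kDa, and recipients were incubated with it for 72 h.

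Per the labels' protocols, polyadenylated RNA was isolated from column-purified total RNA and made into libraries with a broad-range RNA kit. Per the submitters' processing notes, reads were aligned with STAR 2.7.11b to the GRCh38 build. The counting tool, its strand setting and its treatment of reads that match several genes are not given in the sources used here. The values the authors deposited are raw counts per gene, whole numbers with different totals per library, in a table of 62754 entries. Of these entries, 20394 carry a class name in place of a gene symbol and took 0.21% to 0.49% of the counts of a library. The identifiers of 58261 entries (92.8%) matched GENCODE release 29 on GRCh38, which gave the coordinates printed here, and 4493 did not. Because multiply matching reads could have been split or dropped, values of near-identical families (MAGEA, GAGE, SPANX, PAGE and HLA genes) are uncertain, and so are those of overlapping and antisense genes.

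The total count per library ran from 26161357 to 57709494. Within every group the replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.64 to 177.88 over pairs, so no library was counted as a copy of another. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

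Genes were tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with filterByExpr, TMM factors and the quasi-likelihood test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each cell type was fitted alone, and a log2 fold change is PRAME +/- minus PRAME +/+, given with its standard error (SE). Whether the response differed between recipient types was tested as an interaction term over the 4 groups of a pair, in 3 such tests. Levels are CPM, counts scaled to the total count of the library, with the SD between libraries. The test was checked on simulated counts with 200 changed genes per comparison. It recovered 81% of 1.5-fold and 97% of 2-fold changes in the A375 setting over 17874 genes. The values were 48% and 76% in the melanocyte setting over 15644 genes, 34% and 74% in the fibroblast setting over 16656 genes, and 64% and 80% in the endothelial setting over 16444 genes. In the test of a difference between melanocyte and fibroblast responses, over 17527 genes, they were 4% and 45%. False calls made up 6.3%, 9.5%, 8.5%, 14.8% and 3.9% of calls in these settings. All but the last lay above the share of 0.05 at which genes were called. The 4 comparisons of the data called 829 to 7376 genes, more than the 200 changed in the simulation. Recovery and false shares may therefore differ in the data.

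The design, the tests, the 35 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Gene lists with at least 5 tested members were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The fry test and an estimated correlation were alternatives. The lists cover pigment cell, endothelial, lymphatic endothelial, fibroblast, keratinocyte and leukocyte identity, cancer-testis antigens, the AXL-high melanoma state, retinoic acid response, MHC class I and class II, type I interferon, interferon-gamma, NF-kB cytokines, immunosuppressive factors, both cell cycle phases, p53 targets, matrix, TGF-beta response, proteases, angiogenesis, endothelial activation, stress, hypoxia, cholesterol synthesis, respiratory chain, mitochondrial mRNA, ribosomal proteins, vesicle formation, MAPK output, chaperones, NRF2 targets, lysosome and EMT regulators. Beside the count of members called over all genes, the count adjusted over the list alone is given, which takes in both directions.

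The named-gene rule took (a) PRAME, and (b) for each cell type the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups. Further parts were (c) from lists with at least 3 called members, the 3 with the smallest adjusted p, and for identity and quality lists also the 3 most abundant members, (d) 10 genes called in the same direction in at least a pair of the 4 comparisons, by their summed ranks of p, and (e) the 5 genes with the smallest adjusted p in each test of a differing response. Parts b, d and e left out sex-chromosome marker genes, entries without a symbol, clone-named entries and pseudogenes. Genes outside the rule that are named, such as TYR or CDH5, are members of the fixed identity lists shown as levels to check the labels.

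RNA of A375 cells in recipient libraries was estimated from the summed CPM of 10 cancer-testis genes, as a percent of their level in the A375 libraries. The genes were MAGEA4, PRAME, PAGE5, MAGEC2, MAGEA3, MAGEA6, MAGEA12, CSAG1, MAGEA10 and PAGE2. Alternatives set before the data were examined were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, a replicate block, a fit over all groups, an added threshold of 1 on the absolute log2 fold change, fry, an estimated correlation and leaving out each library in turn. Subtraction of the estimated A375 RNA, and leaving out the libraries farthest from their group, were added after seeing the data, as was the exchange of donor labels in the tests of a differing response. The libraries left out were PRAME +/+ replicate 1 and PRAME +/- replicate 3 of the fibroblast-labelled cells, and PRAME +/+ replicate 3 and PRAME +/- replicate 1 of the melanocyte-labelled cells.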

Results

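Polyadenylated RNA was sequenced from A375 melanoma cells of a PRAME +/+ or PRAME +/- genotype, and from recipient cells that had received vesicle preparations of either donor. There were 3 libraries in each of 7 groups and 2 in the endothelial-labelled group given PRAME +/- vesicles. Total counts per library ran from 26161357 to 44622434 in PRAME +/+ and 31321387 to 33819249 in PRAME +/- A375 cells. They ran from 28228299 to 32111398 and from 27143488 to 35874572 in the melanocyte-labelled libraries given PRAME +/+ and PRAME +/- vesicles. The ranges were 42075924 to 56084078 and 44405294 to 57709494 in the fibroblast-labelled libraries. They were 41037513 to 47592721 and 43923286 to 47035125 in the endothelial-labelled libraries. Mitochondrial mRNA took 5.89% ± 2.87 (SD, n = 3) of counts in the fibroblast-labelled PRAME +/- group, where replicate 3 had 9.06%, against 4.24% ± 0.18 in its PRAME +/+ group.

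PRAME (ENSG00000185686.18, chromosome 22, 22547701 to 22559361, minus strand, GRCh38) was the gene that the donor genotype names. In A375 cells it went from 213 ± 6.1 CPM to 200 ± 6.65 CPM (SD, n = 3), a log2 fold change of -0.13 (SE 0.03) and an adjusted p of 0.00192 with edgeR's quasi-likelihood test. The fall was 1.09-fold, and in a fit over all 8 groups it did not pass, at -0.12 with an adjusted p of 0.635. Levels this close leave the genotype of the A375 libraries to their labels, which are used as given. In the recipients PRAME was scarce. It rose from 1.93 ± 0.361 CPM to 5.88 ± 1.2 CPM in the melanocyte-labelled libraries, a log2 fold change of 1.53 (SE 0.21) with an adjusted p of 0.00706, which was 0.0612 without PRAME +/+ replicate 1. It fell from 0.441 ± 0.154 CPM to 0.0995 ± 0.038 CPM in the fibroblast-labelled libraries, a log2 fold change of -1.99 (SE 0.41) with an adjusted p of 0.014, which was 0.0535 without PRAME +/- replicate 1, 0.0531 without PRAME +/- replicate 2 and 0.0553 with a replicate block. In the endothelial-labelled libraries it stood at 0.214 ± 0.0777 CPM with PRAME +/+ vesicles and 0.0539 ± 0.044 CPM (n = 2) with PRAME +/- vesicles, with an adjusted p of 0.0529, which was 0.0453 without PRAME +/+ replicate 2.

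**Figure D1:**
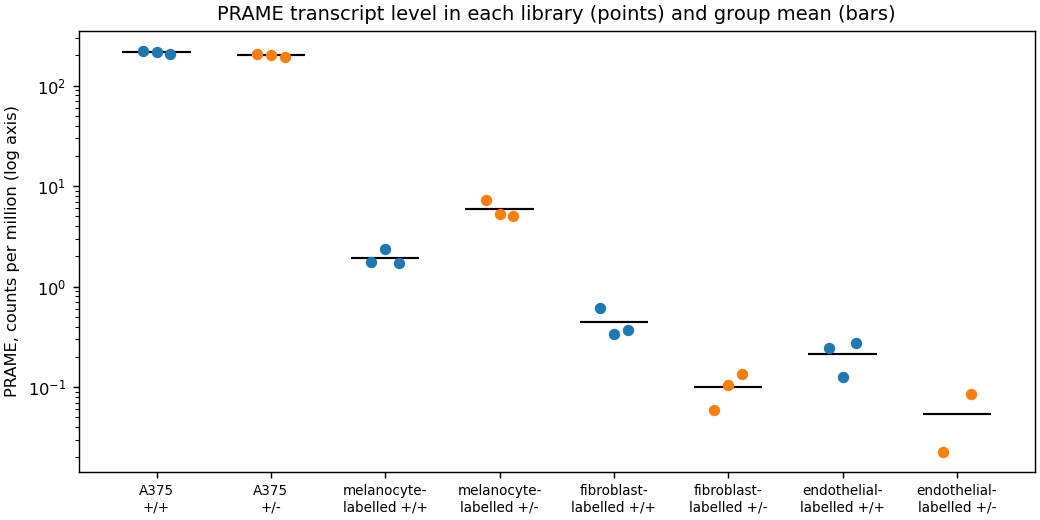
PRAME level (CPM, log axis) in each library, as points, with a bar at the mean of each of the 8 groups. A375 cells of both genotypes stood near 200 CPM, and the recipient groups stood between 0.0539 and 5.88 CPM.

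The share of A375 RNA in the recipients was taken from 10 cancer-testis genes that the A375 libraries carried at high levels, PRAME among them. It was 1.31% ± 0.26 with PRAME +/+ and 3.92% ± 0.632 with PRAME +/- vesicles in the melanocyte-labelled libraries, 3-fold higher. It was 0.273% ± 0.0435 and 0.0562% ± 0.0129 in the fibroblast-labelled libraries, 4.86-fold lower, and 0.179% ± 0.00487 and 0.0505% ± 0.03 (n = 2) in the endothelial-labelled libraries, 3.55-fold lower. The exact permutation p was 0.1 in each recipient type, two-sided, the smallest these designs allow. SOX10, at 1110 and 1090 CPM in A375 cells, stood at 7.9 and 26.7 CPM in melanocyte-labelled libraries. It stood at 1.7 and 0.383 CPM in fibroblast-labelled ones. These levels are below the stated shares of its A375 level. The share is thus that of the 10 genes and may overstate the share of other A375 transcripts.

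Identity markers were set against the labels. The melanocyte-labelled libraries held little of the pigment enzyme TYR (1.76 ± 0.152 CPM with PRAME +/+ and 2.09 ± 0.337 CPM with PRAME +/- vesicles, SD, n = 3), while the fibrillar collagen COL1A2 stood at 3150 ± 30.2 and 2850 ± 103 CPM. The endothelial-labelled libraries held 10.5 ± 1.19 and 10.4 ± 0.865 CPM of the endothelial junction gene PECAM1 and 6.65 ± 0.953 and 6.94 ± 0.737 CPM of the endothelial cadherin CDH5, against 8260 and 8270 CPM of COL1A2. In the melanocyte-labelled libraries PECAM1 stood at 7.8 ± 5.1 and 21.5 ± 9.79 CPM and CDH5 at 0.0118 and 0 CPM, so CDH5 and not PECAM1 set the endothelial-labelled libraries apart from these. In the fibroblast-labelled libraries COL1A2 stood at 8180 and 8290 CPM. Summed over the fibroblast identity list, the level was 7900 and 6790 CPM in melanocyte-labelled, 17500 and 20400 CPM in endothelial-labelled, 26300 and 27800 CPM in fibroblast-labelled and 131 and 144 CPM in A375 libraries. The pigment cell list summed to 518 and 553, 136 and 157, 286 and 188, and 1360 and 1340 CPM in the same order. Its member GPNMB made up 318 and 283 CPM of the melanocyte-labelled sums. PAX3 stood there at 102 and 117 CPM, and at no more than 5.11 CPM in other recipient groups. Recipient groups are therefore named by their labels only.

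**Figure D2:**
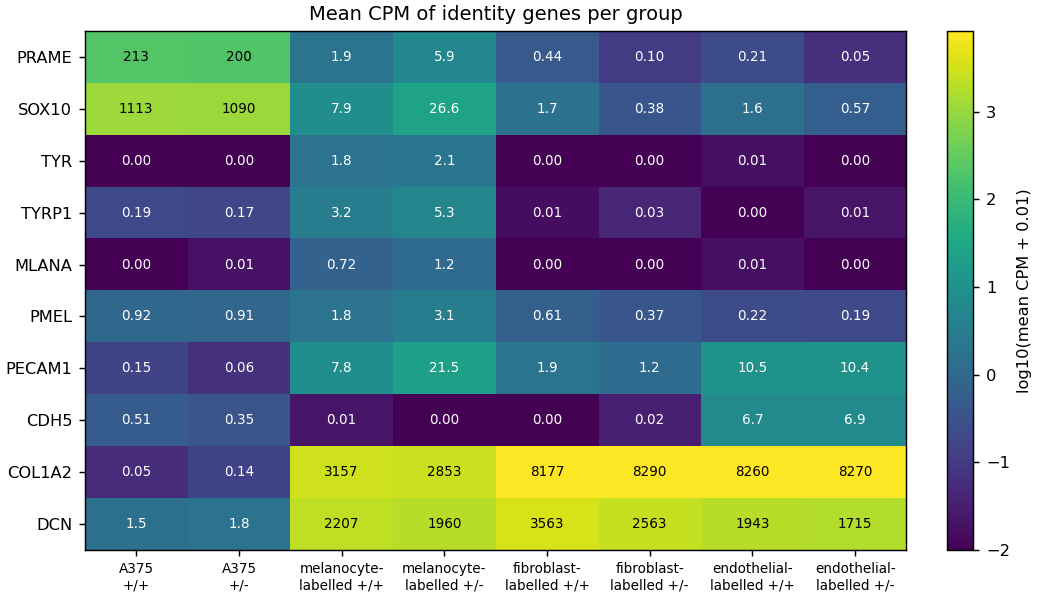
Mean level of PRAME and of pigment cell, endothelial and fibroblast markers in each of the 8 groups, with colour for log10 of the mean CPM plus 0.01. COL1A2 and DCN were high in all recipient groups, and TYR, PECAM1 and CDH5 were low in the groups labelled for their cell types. PECAM1 was highest in the melanocyte-labelled PRAME +/- group, at 21.5 CPM.

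The comparison within A375 asked how the line differed with its PRAME genotype. The inflammatory and matrix-acting genes CXCL8, LCN2 and MMP9 were lower in PRAME +/- cells. The neutrophil chemokine CXCL8 (ENSG00000169429.12, chromosome 4, 73740506 to 73743716, plus strand) fell from 905 ± 54 CPM to 206 ± 3.81 CPM (SD, n = 3 in both groups), a log2 fold change of -2.18 (SE 0.04) with an adjusted p of 1.26e-22 by edgeR's quasi-likelihood test. The gelatinase MMP9 (ENSG00000100985.7, chromosome 20, 46008908 to 46016561, plus strand) fell from 54 ± 4.84 CPM to 1.34 ± 0.222 CPM, at -5.37 (SE 0.10) on the log2 scale, and the iron-scavenging lipocalin LCN2 from 148 ± 18.3 CPM to 6.84 ± 0.301 CPM, at -4.48 (SE 0.08). MME, a membrane peptidase, CD93, CDCP1, a membrane substrate of SRC kinases, and COCH were the other members of the 6 largest falls, at -5.68 (SE 0.31), -5.49 (SE 0.21), -5.40 (SE 0.10) and -5.18 (SE 0.15). The 6 largest rises were in MIR4527HG at 3.08 (SE 0.09), SPANXD at 2.78 (SE 0.17), the monoamine oxidase MAOB at 2.72 (SE 0.13), FAM20A at 2.72 (SE 0.14), the transcription factor CREB5 at 2.71 (SE 0.08) and CSMD1 at 2.63 (SE 0.10). Of 18067 genes tested, 6391 (35.4%) were called, 2883 higher and 3508 lower in PRAME +/- cells, and 829 of them had an absolute log2 fold change of at least 1 (290 higher and 539 lower). A fit over all 8 groups called 1947, 722 higher and 1225 lower. The labels do not say whether either genotype is a clone, so differences between clones would enter these calls.

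Of 27 NF-kB and inflammatory cytokine genes, 26 fell and 1 rose (27 adjusted over the list alone, adjusted p = 0.253 with an estimated correlation, camera adjusted p = 4.26e-21 at the preset value). The growth factor CSF2 went from 56.2 to 4.71 CPM and the chemokine CXCL1 from 405 to 125 CPM. Among endothelial adhesion and activation genes 5 of 8 fell and 1 rose (6 adjusted over the list alone, adjusted p = 0.253 with an estimated correlation, camera adjusted p = 0.00251 at the preset value). The monocyte chemokine CCL2 was at -1.12 (SE 0.04) and the membrane-bound chemokine CX3CL1 at -1.52 (SE 0.12). The interferon-gamma list had 6 of 12 members lower and 0 higher (6 adjusted over the list alone, adjusted p = 0.268 with an estimated correlation, camera adjusted p = 0.00251 at the preset value). The adhesion receptor ICAM1 was at -0.80 (SE 0.03) and the transcription factor IRF1 at -0.62 (SE 0.05). For MHC class I and antigen processing 12 of 20 genes fell and 1 rose (13 adjusted over the list alone, adjusted p = 0.436 with an estimated correlation, camera adjusted p = 0.000825 at the preset value). HLA-B was at -0.47 (SE 0.03) and the light chain B2M at -0.22 (SE 0.03), which did not pass in the fit over all 8 groups (adjusted p = 0.188).

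The dedifferentiated, AXL-high list had 11 of 16 genes lower and 1 higher (12 adjusted over the list alone, adjusted p = 0.268 with an estimated correlation, camera adjusted p = 0.000825 at the preset value). The AP-1 factor FOSL1 went from 529 to 299 CPM. Matrix genes fell in 11 and rose in 4 of 20 (17 adjusted over the list alone, adjusted p = 0.408 with an estimated correlation, camera adjusted p = 0.0369 at the preset value). That p was 0.063 without PRAME +/- replicate 2. The basement membrane collagens COL4A1 and COL4A2 were at -0.93 (SE 0.03) and -0.86 (SE 0.03), and COL6A3 at -3.03 (SE 0.09). Matrix proteases fell in 7 and rose in 2 of 15 (9 adjusted over the list alone, adjusted p = 0.436 with an estimated correlation, camera adjusted p = 0.0369 at the preset value). That p was 0.0743 without PRAME +/+ replicate 1. Of 16 cholesterol synthesis genes 12 fell and 3 rose (15 adjusted over the list alone, adjusted p = 0.604 with an estimated correlation, camera adjusted p = 0.00251 at the preset value). They included the sterol sensor partner INSIG1 at -0.74 (SE 0.04). Vesicle formation genes fell in 11 and rose in 2 of 21 (14 adjusted over the list alone, adjusted p = 0.473 with an estimated correlation, camera adjusted p = 0.00966 at the preset value). The syndecan SDC4, which takes part in exosome formation, went from 513 to 236 CPM, and the tetraspanin CD82 from 30.2 to 10.8 CPM. Among p53 targets 13 of 21 rose and 3 fell (16 adjusted over the list alone, adjusted p = 0.253 with an estimated correlation, camera adjusted p = 0.000825 at the preset value). The stress cytokine GDF15 was at 1.58 (SE 0.09) and the cell cycle inhibitor CDKN1A at 0.57 (SE 0.04), while the death receptor TNFRSF10B was at -0.41 (SE 0.03). The TGF-beta list was not called (10 of 18 fell, 4 rose, camera adjusted p = 0.096). That p was 0.0488 without PRAME +/- replicate 1.

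The melanocyte-labelled comparison asked how these cells differed after PRAME +/- against PRAME +/+ vesicles. The interferon-induced genes IFI6 and MX1 rose and the matrix gene POSTN fell. IFI6 (ENSG00000126709.16, chromosome 1, 27666061 to 27672218, minus strand), an interferon-induced protein of mitochondria and endoplasmic reticulum, rose from 26.8 ± 1.47 CPM to 143 ± 4.03 CPM (SD, n = 3 in both groups), a log2 fold change of 2.34 (SE 0.07) with an adjusted p of 7.13e-06 by edgeR's quasi-likelihood test. The antiviral GTPase MX1 went from 8.25 ± 1.12 CPM to 50.4 ± 0.596 CPM, by 2.54 (SE 0.10). POSTN (ENSG00000133110.15, chromosome 13, 37562583 to 37598844, minus strand), a matrix protein induced by TGF-beta, fell from 44 ± 14.8 CPM to 0.9 ± 0.478 CPM, at -5.64 (SE 0.39) with an adjusted p of 0.00045. The 6 largest rises were in ADH1B at 3.83 (SE 0.62), the metalloreductase STEAP4 at 3.45 (SE 0.43), FDCSP at 3.31 (SE 0.26), the antiviral synthetases OAS1 and OAS2 at 3.18 (SE 0.24) and 3.08 (SE 0.19), and IFIT1 at 2.75 (SE 0.14). The largest falls after POSTN were in the Wnt pathway gene DACT1 at -3.87 (SE 0.29), SCG5 at -3.08 (SE 0.29), the receptor kinase ROS1 at -2.85 (SE 0.28), LINC00862 at -2.66 (SE 0.26) and LRRC15, a marker of myofibroblasts, at -2.53 (SE 0.52). ADH1B had an adjusted p of 0.0137, which was 0.0937 without PRAME +/+ replicate 1, 0.0513 without PRAME +/+ replicate 2 and 0.0729 without PRAME +/- replicate 3, and LRRC15 had 0.031, then 0.144, 0.135 and 0.143, and 0.0859 with limma-voom. Of 15985 genes tested, 829 (5.2%) were called, 498 higher and 331 lower, and 321 with an absolute log2 fold change of at least 1 (226 higher and 95 lower). The count was 143 without PRAME +/+ replicate 1, 172 without PRAME +/+ replicate 2, 230 without PRAME +/- replicate 3 and 1506 without PRAME +/- replicate 2.

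Of 30 type I interferon response genes 25 rose and 0 fell (26 adjusted over the list alone, adjusted p = 0.00903 with an estimated correlation, camera adjusted p = 7.27e-31 at the preset value). Over all 4 comparisons this was the single list call that held with an estimated correlation. MHC class II genes rose in 6 of 9 (8 adjusted over the list alone, adjusted p = 0.206 with an estimated correlation, camera adjusted p = 3.86e-10 at the preset value). The class II transactivator CIITA went from 2.3 to 13.8 CPM and the invariant chain CD74 from 23.8 ± 4.27 CPM to 99.3 ± 23.6 CPM. A375 cells held 2180 CPM of CD74 with PRAME +/+ and 2000 CPM with PRAME +/-, and the A375 share was 3-fold higher in the same group. Cancer-testis genes rose in 9 of 10 (10 adjusted over the list alone, adjusted p = 0.206 with an estimated correlation, camera adjusted p = 3.1e-12 at the preset value), MAGEA4 from 7.1 to 23.1 CPM. MAGEA4 did not pass after subtraction of A375 RNA (adjusted p = 0.0695), an alternative chosen after seeing the data. The cancer-testis list holds the 10 genes that set the A375 share, MAGEA4 among them. The rise of the list and the 3-fold higher share are therefore not independent. For the same reason the lost call of MAGEA4 cannot test A375 RNA as the source. MHC class I and antigen processing genes rose in 5 of 20 and fell in 0 (9 adjusted over the list alone, 8 higher and 1 lower, adjusted p = 0.428 with an estimated correlation, camera adjusted p = 4.19e-05 at the preset value). The peptide transporter TAP1 was at 0.52 (SE 0.08), and its adjusted p of 0.0123 was 0.0801 without PRAME +/+ replicate 1 and 0.054 without PRAME +/- replicate 3. The interferon-gamma list rose in 2 of 11 (3 adjusted over the list alone, adjusted p = 0.338 with an estimated correlation, camera adjusted p = 0.0233 at the preset value). That camera p was 0.181 without PRAME +/+ replicate 3, 0.0594 without PRAME +/- replicate 1 and 0.143 without PRAME +/- replicate 2.

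The myofibroblast and TGF-beta list fell in 11 of 18 genes and rose in 0 (12 adjusted over the list alone, 11 lower and 1 higher, adjusted p = 0.206 with an estimated correlation, camera adjusted p = 1.24e-06 at the preset value). LTBP2, a binder of microfibrils, went from 477 to 229 CPM and the feedback inhibitor SMAD7 was at -0.88 (SE 0.09). Matrix genes fell in 9 and rose in 1 of 23 (18 adjusted over the list alone, adjusted p = 0.206 with an estimated correlation, camera adjusted p = 3.86e-10 at the preset value). COL5A1 was at -0.98 (SE 0.09) and the proteoglycan VCAN at -1.04 (SE 0.14). Of 12 fibroblast identity genes 3 fell and 0 rose (8 adjusted over the list alone, 5 lower and 3 higher, camera adjusted p = 0.488), and their summed level went from 7900 ± 176 to 6790 ± 169 CPM. The members that fell were the peptidase FAP from 367 to 183 CPM, COL1A1 from 1500 to 993 CPM and the proteoglycan LUM from 12.9 to 9.1 CPM. Their adjusted p of 0.013, 0.0372 and 0.0295 was 0.0755, 0.176 and 0.121 without PRAME +/+ replicate 1, 0.0692, 0.165 and 0.109 without PRAME +/+ replicate 2, and 0.0597, 0.154 and 0.141 without PRAME +/- replicate 3. That of LUM was 0.0699 without PRAME +/+ replicate 3 and 0.0734 with a replicate block, and that of COL1A1 was 0.0646 after subtraction of A375 RNA. The AXL-high list fell in 4 of 16 (8 adjusted over the list alone, adjusted p = 0.206 with an estimated correlation, camera adjusted p = 0.000699 at the preset value). Its fibronectin gene FN1 went from 72000 to 47500 CPM with an adjusted p of 0.0126, which was 0.0856 without PRAME +/+ replicate 1, 0.0675 without PRAME +/+ replicate 2, 0.0626 without PRAME +/- replicate 3 and 0.0539 with a replicate block. EMT regulators fell in 2 of 12 (6 adjusted over the list alone, 4 lower and 2 higher, adjusted p = 0.338 with an estimated correlation, camera adjusted p = 0.0223 at the preset value). That p was 0.0539 without PRAME +/- replicate 3. In G2/M and mitosis 1 of 22 genes fell (1 adjusted over the list alone, adjusted p = 0.5 with an estimated correlation, camera adjusted p = 3.36e-06 at the preset value). In G1/S 0 of 23 did (0 adjusted over the list alone, adjusted p = 0.572 with an estimated correlation, camera adjusted p = 0.00204 at the preset value). That p was 0.131 without PRAME +/- replicate 1. Both lists were called on small shifts of many members, with medians of -0.31 and -0.17. The pigment cell list rose in 2 of 17 (3 adjusted over the list alone, adjusted p = 0.361 with an estimated correlation, camera adjusted p = 0.0233 at the preset value). That p was 0.0625 without PRAME +/+ replicate 2 and 0.105 without PRAME +/- replicate 2. Its member SOX10 went from 7.9 ± 1.34 to 26.7 ± 10 CPM, while A375 cells held 1110 and 1090 CPM of SOX10 and the A375 share was 3-fold higher in the same group. For p53 targets 2 of 22 rose (3 adjusted over the list alone, adjusted p = 0.206 with an estimated correlation, camera adjusted p = 0.017 at the preset value). That p was 0.087 without PRAME +/+ replicate 3 and 0.0959 without PRAME +/- replicate 2. Ribosomal protein genes had 0 of 24 called and a median of 0.09 (0 adjusted over the list alone, adjusted p = 0.641 with an estimated correlation, camera adjusted p = 0.00562 at the preset value). That p was 0.249 without PRAME +/- replicate 2. Respiratory chain genes had 0 of 20 called and a median of 0.12 (0 adjusted over the list alone, adjusted p = 0.641 with an estimated correlation, camera adjusted p = 0.0233 at the preset value). That p was 0.0989, 0.0543 and 0.336 without PRAME +/+ replicate 1, PRAME +/+ replicate 2 and PRAME +/- replicate 2.

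The fibroblast-labelled comparison asked the same of cells labelled as dermal fibroblasts. ANGPTL4 and the matrix gene POSTN rose, and the metalloreductase STEAP4 fell. STEAP4 (ENSG00000127954.13, chromosome 7, 88270892 to 88306891, minus strand) fell from 148 ± 11.9 CPM to 0.686 ± 0.198 CPM (SD, n = 3 in both groups), a log2 fold change of -7.62 (SE 0.19) with an adjusted p of 9.99e-07 by edgeR's quasi-likelihood test. ANGPTL4 (ENSG00000167772.12, chromosome 19, 8363289 to 8374373, plus strand), an inhibitor of lipoprotein lipase, rose from 49.5 ± 5.76 CPM to 399 ± 35.2 CPM, by 3.13 (SE 0.12) with an adjusted p of 9.22e-06. POSTN rose from 39.5 ± 4.93 CPM to 238 ± 63.1 CPM, by 2.71 (SE 0.22). Other members of the 6 largest rises were SERPINA9 at 5.46 (SE 0.22), the scavenging chemokine receptor ACKR3 at 3.25 (SE 0.18), the cation transporter SLC22A3 at 3.11 (SE 0.16), the TGF-beta target PMEPA1 at 3 (SE 0.13) and LRRC15 at 2.82 (SE 0.26). The largest falls after STEAP4 were in ADH1B at -6.76 (SE 0.20), COL14A1 at -4.31 (SE 0.20), RIPOR2 at -3.64 (SE 0.19), the chemokine CCL13 at -3.60 (SE 0.25) and the hyaluronan receptor LYVE1 at -3.55 (SE 0.23). Of 16975 genes tested, 2584 (15.2%) were called, 1271 higher and 1313 lower, and 894 with an absolute log2 fold change of at least 1 (382 higher and 512 lower). The count was 1140 without PRAME +/+ replicate 2, 1276 without PRAME +/+ replicate 3, 1721 without PRAME +/- replicate 1 and 1570 without PRAME +/- replicate 2.

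Of 20 myofibroblast and TGF-beta genes 12 rose and 0 fell (14 adjusted over the list alone, 13 higher and 1 lower, adjusted p = 0.247 with an estimated correlation, camera adjusted p = 4.37e-06 at the preset value). The matrix protein TGFBI went from 2830 to 8070 CPM and the tropomyosin TPM1 from 229 to 831 CPM. Hypoxia and glycolysis genes rose in 9 and fell in 1 of 16 (12 adjusted over the list alone, adjusted p = 0.672 with an estimated correlation, camera adjusted p = 1.23e-05 at the preset value). The glycolytic regulator PFKFB4 was at 1.28 (SE 0.12) and the angiogenic factor VEGFA at 0.98 (SE 0.12). Mitochondrial mRNA, at a median log2 fold change of 0.63, had 0 of 13 genes called (0 adjusted over the list alone, camera adjusted p = 0.0543). That p was 0.0394 without PRAME +/+ replicate 2, 2.28e-05 without PRAME +/- replicate 1 and 0.0467 without PRAME +/- replicate 2. EMT regulators rose in 5 of 11 (5 adjusted over the list alone, adjusted p = 0.672 with an estimated correlation, camera adjusted p = 0.00991 at the preset value). The cadherin CDH2 was at 2.44 (SE 0.18) and the integrin ITGB3 at 1.40 (SE 0.14). Type I interferon genes fell in 16 of 30 (17 adjusted over the list alone, adjusted p = 0.672 with an estimated correlation, camera adjusted p = 4.37e-06 at the preset value). IFIT3 went from 32.1 to 14.4 CPM, and MX2 was at -1.36 (SE 0.20). The interferon-gamma list fell in 4 of 11 (5 adjusted over the list alone, adjusted p = 0.672 with an estimated correlation, camera adjusted p = 0.0405 at the preset value). That p was 0.0755 without PRAME +/+ replicate 1 and 0.099 without PRAME +/- replicate 3. MHC class I genes fell in 5 of 20 (8 adjusted over the list alone, adjusted p = 0.672 with an estimated correlation, camera adjusted p = 0.0243 at the preset value), TAP2 at -0.64 (SE 0.11). MHC class II genes fell in 3 of 6 (3 adjusted over the list alone, adjusted p = 0.672 with an estimated correlation, camera adjusted p = 0.0372 at the preset value). That p was 0.0755 without PRAME +/+ replicate 1. CD74 went from 5.32 to 1.45 CPM. The A375 share was 4.86-fold lower in the same group. The pigment cell list fell in 5 of 11 (7 adjusted over the list alone, adjusted p = 0.247 with an estimated correlation, camera adjusted p = 0.000226 at the preset value). Its members that fell included the endothelin receptor EDNRB at -2.62 (SE 0.15) and the receptor kinase KIT at -2.81 (SE 0.28), which are not restricted to pigment cells. Among cancer-testis genes 3 of 3 tested fell (3 adjusted over the list alone), MAGEA4 at -2.44 (SE 0.27). This list holds the 10 genes that set the A375 share, MAGEA4 among them. Its fall and the 4.86-fold lower share are therefore not independent.

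The endothelial-labelled comparison asked the same question with 3 against 2 libraries. The tropomyosin TPM1 rose, and the interferon-induced IFI6 fell. TPM1 (ENSG00000140416.25, chromosome 15, 63042632 to 63071915, plus strand) rose from 155 ± 10 CPM to 641 ± 26.2 CPM (SD, n = 3 and 2), a log2 fold change of 2.09 (SE 0.07) with an adjusted p of 1.02e-07 by edgeR's quasi-likelihood test. IFI6 fell from 197 ± 19.2 CPM to 30.5 ± 9.78 CPM, at -2.64 (SE 0.18) with an adjusted p of 3.91e-06, and SERPINB2, an inhibitor of plasminogen activators, from 282 ± 25.5 CPM to 31.3 ± 0.629 CPM, at -3.12 (SE 0.10). The 6 largest rises were in the transcription factor ASCL2 at 4.91 (SE 0.27), DRAXIN at 4.80 (SE 0.28), the protease-activated receptor F2RL1 at 4.49 (SE 0.17), ZPLD1 at 4.24 (SE 0.20), AMIGO2 at 3.99 (SE 0.17) and BAIAP3 at 3.91 (SE 0.25). The largest falls were in the keratin KRT23 at -4.04 (SE 0.24), FER1L6 at -3.92 (SE 0.26), TNXB at -3.18 (SE 0.14), the oxysterol hydroxylase CYP7B1 at -2.96 (SE 0.14) and the pyruvate dehydrogenase kinase PDK4 at -2.94 (SE 0.09), beside SERPINB2. Of 16883 genes tested, 7376 (43.7%) were called, 3322 higher and 4054 lower, and 1655 with an absolute log2 fold change of at least 1. Of these 1118 were higher and 537 lower, so the majority lay the other way among the larger changes. Without PRAME +/- replicate 1, which leaves a lone library assumed to vary like the other group, the count was 4567.

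Of 19 myofibroblast and TGF-beta genes 18 rose and 0 fell (18 adjusted over the list alone, adjusted p = 0.682 with an estimated correlation, camera adjusted p = 1.76e-08 at the preset value). The smooth muscle gene TAGLN went from 34.5 to 90.5 CPM, and CTHRC1 was at 1.35 (SE 0.07). Hypoxia and glycolysis genes rose in 11 and fell in 1 of 16 (13 adjusted over the list alone, adjusted p = 0.682 with an estimated correlation, camera adjusted p = 0.00183 at the preset value). The carbonic anhydrase CA9 was at 2.33 (SE 0.16) and VEGFA at 0.99 (SE 0.09). Unfolded protein and integrated stress response genes rose in 8 and fell in 1 of 17 (10 adjusted over the list alone, adjusted p = 0.682 with an estimated correlation, camera adjusted p = 0.00664 at the preset value). The serine synthesis enzyme PHGDH was at 1.29 (SE 0.08) and the cystine transporter SLC7A11 at -1.27 (SE 0.08). Mitochondrial mRNA rose in 9 of 13 (10 adjusted over the list alone, adjusted p = 0.682 with an estimated correlation, camera adjusted p = 0.0118 at the preset value). That p was 0.0552 without PRAME +/+ replicate 1 and 0.0832 without PRAME +/- replicate 1. The share of mitochondrial mRNA was 4.33% ± 0.39 and 5.73% ± 1.36. Ribosomal protein genes rose in 8 of 24 (1 adjusted over the list alone, adjusted p = 0.682 with an estimated correlation, camera adjusted p = 0.0122 at the preset value). That p was 0.0823 without PRAME +/- replicate 1. Type I interferon genes fell in 18 and rose in 4 of 31 (24 adjusted over the list alone, adjusted p = 0.682 with an estimated correlation, camera adjusted p = 0.0264 at the preset value). The interferon-induced gene IFI27 was at -2.17 (SE 0.17). The A375 share was 3.55-fold lower in the same group. G1/S genes fell in 14 of 23 (15 adjusted over the list alone, adjusted p = 0.682 with an estimated correlation, camera adjusted p = 0.00613 at the preset value). The ribonucleotide reductase subunit RRM2 was at -0.60 (SE 0.07). G2/M genes fell in 11 and rose in 1 of 22 (13 adjusted over the list alone, adjusted p = 0.682 with an estimated correlation, camera adjusted p = 0.0118 at the preset value), with the topoisomerase TOP2A at -0.63 (SE 0.08). The camera p was 0.055 without PRAME +/+ replicate 3 and 0.0628 without PRAME +/- replicate 2. MAPK output genes fell in 13 and rose in 2 of 19 (15 adjusted over the list alone, adjusted p = 0.682 with an estimated correlation, camera adjusted p = 0.0118 at the preset value). The feedback inhibitor SPRY2 was at -1.14 (SE 0.08) and the ETS factor ETV1 at -0.90 (SE 0.08).

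**Figure D3:**
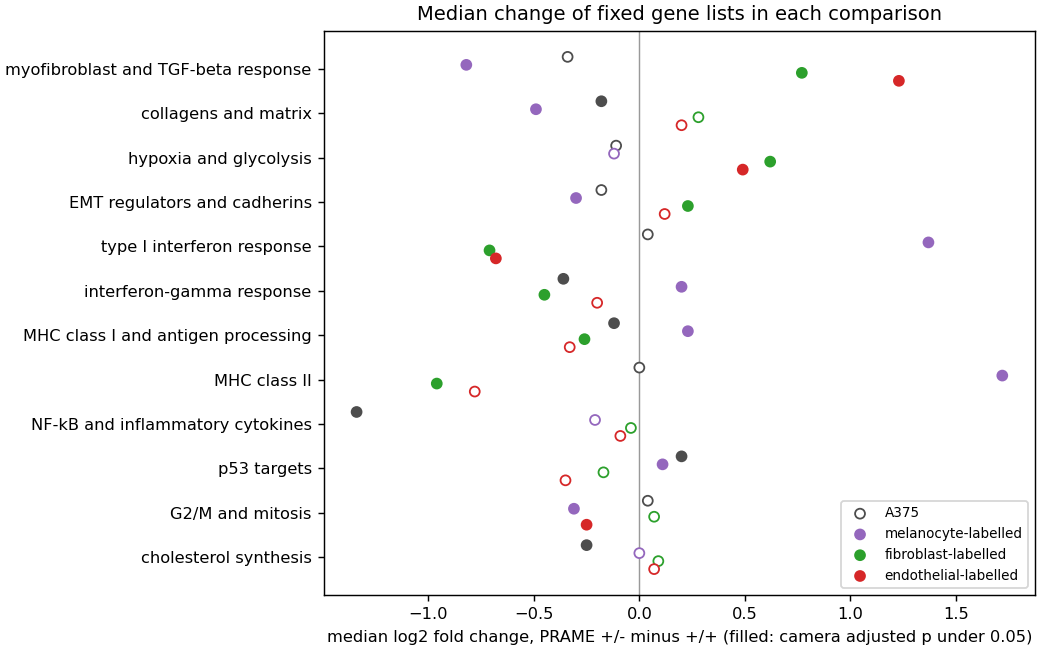
Median log2 fold change (PRAME +/- minus PRAME +/+) of 12 fixed gene lists in the 4 comparisons, with filled points for lists called by camera at the preset correlation. The myofibroblast and TGF-beta list lay at -0.82 in the melanocyte-labelled, 0.77 in the fibroblast-labelled and 1.23 in the endothelial-labelled comparison.

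The calls of the comparisons were then set side by side. Genes called in both the melanocyte- and the fibroblast-labelled comparison went in opposite directions in 426 of 439 cases (97%), where 56.4 opposite calls were expected from the counts, and 13 went the same way, where 56.6 were expected. These directions take the donor labels as given, and with those of the fibroblast-labelled libraries exchanged 426 would go the same way and 13 opposite. An exchange was not excluded there. Transcripts counted as restricted to A375 cells had at least 10 CPM there. In the fibroblast- or endothelial-labelled type not being tested they had under 1% of that level. Among these transcripts, those higher in PRAME +/- A375 cells differed from those lower by a median log2 value of -0.91 in fibroblast-labelled libraries (permutation p = 0.155). In A375 itself these genes differed by 2.64. In endothelial-labelled libraries the value was -0.93 (permutation p = 0.0807), against 2.5 in A375. The permutation shuffled genes between the higher and lower sets, so its p carries no spread between libraries. POSTN, PMEPA1 and ANGPTL4 fell in melanocyte-labelled and rose in fibroblast-labelled libraries, and STEAP4 and CD74 did the reverse. The estimated A375 share accounted for 72.3% of the CD74 rise in melanocyte-labelled libraries. In fibroblast-labelled libraries that share was 4.86-fold lower with PRAME +/- vesicles. The changes of CD74 may therefore be in part those of A375 RNA. Between the melanocyte- and endothelial-labelled comparisons 495 of 545 (90.8%) were opposite, where 171.9 were expected, and 50 the same, where 164.1 were expected, and with the endothelial donor labels exchanged 495 would go the same way and 50 opposite. Between the fibroblast- and endothelial-labelled comparisons 1730 genes went the same way, where 528.9 were expected, and 47 opposite, where 531.8 were expected. PMEPA1, LMCD1, a repressor of GATA factors, the transcription factor SOX4 and DGKI were higher in both, and the estrogen-metabolising CYP1B1 and PDK4 were lower. Across genes the Spearman correlations of the log2 fold changes were -0.29, -0.21 and 0.63 for these 3 pairs, and genes are not independent replicates. A375 calls shared 342 same-direction and 152 opposite calls with the melanocyte-labelled comparison, where 135 and 142.1 were expected. They shared 371 and 754 with the fibroblast-labelled (389.4 and 391.3 expected), and 1210 and 1641 with the endothelial-labelled comparison (1227.6 and 1186.8 expected). With the recipient labels exchanged, the same-direction and opposite counts of these last 2 pairs would trade places. Across the 3 recipient types 171 genes were lower in melanocyte-labelled and higher in both others, 181 were the reverse, 2 were higher in all 3 and 5 lower in all 3. With both the fibroblast and endothelial donor labels exchanged, the 171 would be lower and the 181 higher in all 3.

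**Figure D4:**
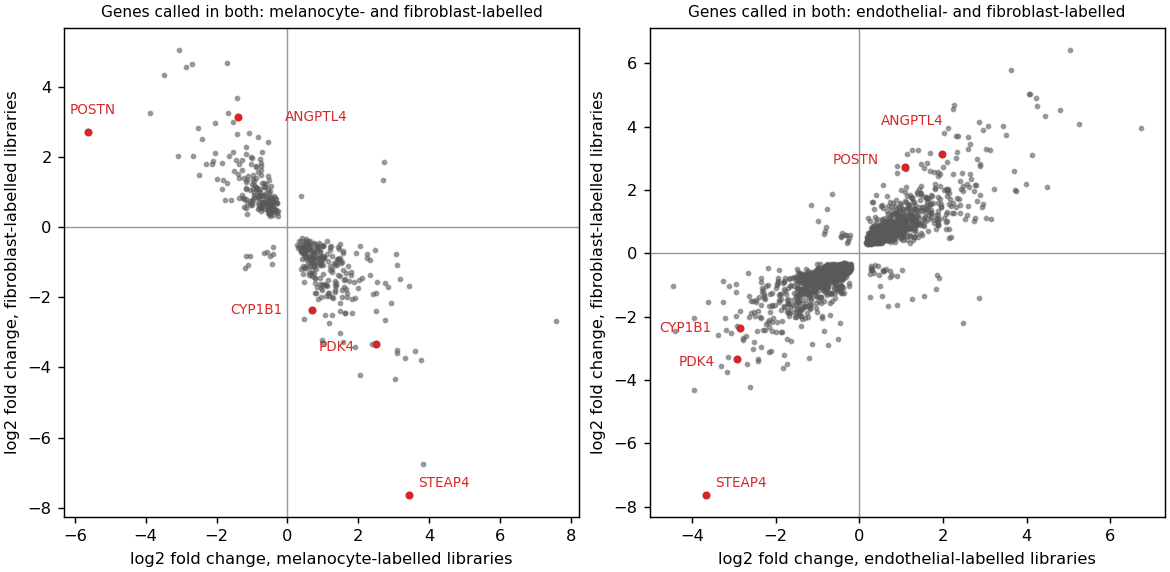
Log2 fold change (PRAME +/- minus PRAME +/+) of genes called in both comparisons of a pair, with melanocyte-labelled against fibroblast-labelled libraries on the left and endothelial-labelled against fibroblast-labelled libraries on the right, and each point a gene. On the left 426 of 439 genes had opposite signs, and on the right 1730 genes had the same sign and 47 opposite signs.

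Whether recipient types responded differently was tested as an interaction with edgeR's quasi-likelihood test. Type I interferon genes differed between the melanocyte- and fibroblast-labelled responses in 26 of 31 members, all higher in the former (28 adjusted over the list alone, adjusted p = 0.0398 with an estimated correlation, camera adjusted p = 2.05e-22 at the preset value). TGF-beta genes differed in 13 of 20, all lower (15 in either direction adjusted over the list alone, adjusted p = 0.0398 with an estimated correlation, camera adjusted p = 2.35e-08 at the preset value). These were the list calls of the interaction tests that held with an estimated correlation. With the fibroblast donor labels exchanged, a test chosen after the results were seen, 10 of 31 interferon genes were higher and 0 lower (16 adjusted over the list alone, adjusted p = 0.702 with an estimated correlation, camera adjusted p = 1.63e-08 at the preset value). Of 20 TGF-beta genes 2 were then higher and 1 lower (5 adjusted over the list alone, camera adjusted p = 0.989). Against the endothelial-labelled response, 25 of 31 type I interferon genes were higher (26 adjusted over the list alone, adjusted p = 0.178 with an estimated correlation, camera adjusted p = 2.31e-14 at the preset value), and 14 of 19 TGF-beta genes lower and 1 higher (16 adjusted over the list alone, adjusted p = 0.144 with an estimated correlation, camera adjusted p = 2.63e-10 at the preset value). With the endothelial donor labels exchanged, 11 of 31 interferon genes were higher and 1 lower (19 adjusted over the list alone, adjusted p = 0.574 with an estimated correlation, camera adjusted p = 6.48e-05 at the preset value), and 8 of 19 TGF-beta genes higher and 1 lower (12 adjusted over the list alone, adjusted p = 0.574 with an estimated correlation, camera adjusted p = 0.0489 at the preset value). Between the fibroblast- and endothelial-labelled responses G2/M genes had 0 of 22 called and a median of 0.34 (0 adjusted over the list alone, adjusted p = 0.688 with an estimated correlation, camera adjusted p = 0.000148 at the preset value), and fry gave an adjusted p of 0.125. The numbers of genes called were 2890 of 17819 (1531 higher and 1359 lower) for melanocyte against fibroblast, 4626 of 18092 (2539 and 2087) for melanocyte against endothelial, and 397 of 18345 (171 and 226) for fibroblast against endothelial. Without fibroblast-labelled PRAME +/- replicate 3 the majority in the last test turned, with 1293 higher and 746 lower. With the fibroblast donor labels exchanged 488 genes were called for melanocyte against fibroblast, and with the endothelial ones exchanged 2457 for melanocyte against endothelial. Without endothelial-labelled PRAME +/- replicate 1 the count for melanocyte against endothelial was 2987. That for fibroblast against endothelial was 221, 225, 195 and 110 without endothelial-labelled PRAME +/+ replicates 2 and 3 and PRAME +/- replicates 1 and 2, and 225, 260 and 2039 without fibroblast-labelled PRAME +/+ replicate 2 and PRAME +/- replicates 1 and 3.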

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

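The tests of explanations for opposite directions were all chosen after the result was seen. A differing response between recipient types, by a test of the difference itself with edgeR, set apart the following results. Between the melanocyte- and fibroblast-labelled libraries 2890 genes differed in their response, and the 5 with the smallest adjusted p were ANGPTL4 with a difference in log2 fold change of -4.52, STEAP4 with 11.08, ACKR3 with -4.93, PMEPA1 with -4.53 and ARHGAP6 with 3.58. Between the melanocyte- and endothelial-labelled libraries 4626 genes differed, led by ANGPTL4 with -3.41, CYP1B1 with 3.52, the basement membrane gene NID2 with 3.07, ACKR3 with -4.82 and IFI6 with 4.97. Between the fibroblast- and endothelial-labelled libraries 397 genes differed, led by the alarmin IL33 with 2.67, the chemokine CXCL12 with -2.35, the plasminogen activator PLAU with 1.7, IGFBP5, a binder of insulin-like growth factors, with -4.3 and the potassium channel subunit KCNG1 with 1.82. With the donor labels of the fibroblast-labelled libraries exchanged 488 genes differed from the melanocyte-labelled response, and with those of the endothelial-labelled ones exchanged 2457.

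The pattern behind the larger counts was the opposite direction of genes called in the melanocyte-labelled against the fibroblast- and endothelial-labelled comparisons. RNA of A375 cells as the whole cause was argued against, since melanocyte against fibroblast had 359 opposite calls after its subtraction, against 426 without it and 56.4 expected. An exchange of donor labels predicts that transcripts restricted to A375 cells carry the other donor's profile. Transcripts counted as restricted had at least 10 CPM in A375 cells. In fibroblast- and endothelial-labelled groups other than the tested type they had under 1% of that level. The tested type itself did not enter this rule, so genes that its cells express could pass. In the melanocyte-labelled libraries the 12 such genes higher in PRAME +/- A375 cells exceeded the 10 lower there by 2.23, against 3.21 in A375 itself. This median log2 difference (permutation p = 0.00375) argues against an exchange there, as far as these transcripts came from A375 cells. It also takes the labels of the A375 libraries as given, which PRAME levels could not check. With the A375 labels exchanged, the sign of the difference would turn in every recipient type. The permutations shuffled genes between the higher and lower sets, with counts pooled over libraries. Their p-values take genes as independent replicates and carry no spread between libraries. In the fibroblast- and endothelial-labelled libraries the same difference was -0.91 (permutation p = 0.155) and -0.93 (permutation p = 0.0807), with the sign an exchange would give but on transcripts near the floor, so exchanged donor labels there could not be excluded and cannot be told apart from a true difference between recipient types. A response that differs by recipient cell type, which the design names, may also account for the pattern and stays open. The tests of a differing response take the donor labels as given, so they cannot tell it from an exchange. With the labels exchanged, 488 genes in fibroblast- and 2457 in endothelial-labelled libraries still differed from the melanocyte-labelled response.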

How the results depend on the processing

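Leaving out the libraries apart from their group, subtracting A375 RNA and exchanging donor labels were chosen after seeing the data, and all other alternatives before. No called named gene, and no called list of the 4 comparisons, reversed direction under the processing alternatives. For fibroblast against endothelial the majority turned, from 171 higher and 226 lower calls to 1293 and 746 without fibroblast-labelled PRAME +/- replicate 3. Without the libraries apart from their group these calls were 1239 higher and 805 lower. With the endothelial donor labels exchanged, which turns that arm by construction, the TGF-beta list for melanocyte against endothelial reversed, from a median of -2.09 (camera adjusted p = 2.63e-10) to 0.41 (camera adjusted p = 0.0489). Of the counts of called genes under alternatives, 80 stayed within 1.5 times the reported count and 34 did not. Over all pairs of a gene list and an alternative in the 4 comparisons, 1406 kept their side of the threshold, called or uncalled. In 83 pairs a call was lost and in 78 gained. The estimated correlation made 41 of these losses and left a single list call. Over all pairs of a named gene and an alternative, 5456 kept their side, 267 were lost and 50 gained. With an added absolute log2 fold change of at least 1, which can only lower a count, 829 genes were called in A375, 321 in the melanocyte-labelled, 894 in the fibroblast-labelled and 1655 in the endothelial-labelled comparison. A fit over all 8 groups called 1947 in A375, 1922 in melanocyte-labelled and 4991 in fibroblast-labelled libraries, and the cause was not tested. With no filter on low counts the melanocyte-labelled count was 1948 and that for fibroblast against endothelial 1007, and with DESeq2 these were 1269 and 712, and the cause was not tested. With a replicate block, which takes residual degrees of freedom, the fibroblast-labelled count was 1309 and that for fibroblast against endothelial 53, and replicate numbers did not pair the libraries, with correlations across genes, between the residuals of libraries of the same number, of -0.39 to 0.29 in the fibroblast-labelled groups. Without the libraries apart from their group 1662 genes were called in the melanocyte-labelled and 6674 in the fibroblast-labelled comparison, and 5164 and 2044 for melanocyte against fibroblast and fibroblast against endothelial. Leaving out each library in turn gave 5191 to 6468 genes in A375, 143 to 1506 in melanocyte-labelled, 1140 to 3499 in fibroblast-labelled and 4567 to 8247 in endothelial-labelled libraries. It gave 2058 to 3172 for melanocyte against fibroblast, 2987 to 6171 for melanocyte against endothelial and 110 to 2039 for fibroblast against endothelial. Genes shared by A375 and fibroblast-labelled calls numbered 218 in the same and 414 in opposite directions with the block. Same-direction calls of the melanocyte- and fibroblast-labelled comparisons were 34 with DESeq2 and 7 with the block, and those of the melanocyte- and endothelial-labelled comparisons 87 with DESeq2. With the block 954 same-direction and 22 opposite calls were shared by the fibroblast- and endothelial-labelled comparisons. PRAME in A375 was at -0.12 (adjusted p = 0.635) in the fit over all 8 groups, whose spread takes in the recipient groups. In fibroblast-labelled libraries it was at -1.97 (adjusted p = 0.0553) with the block. In endothelial-labelled libraries it was at -1.89 (adjusted p = 0.0488) with no filter and -1.86 (adjusted p = 0.0213) in the fit over all 8 groups. Leaving out each library gave PRAME values of -0.15 to -0.11 in A375, 1.37 to 1.69 in melanocyte-labelled, -2.23 to -1.72 in fibroblast-labelled and -3.05 to -1.25 in endothelial-labelled libraries, and no PRAME value was had after subtraction of A375 RNA, since it then fell under the low-count filter. Fry gained 30 list calls in the 4 comparisons. With fry 10 list calls of the 4 comparisons and 6 of the tests of a differing response were lost. In melanocyte-labelled libraries these were pigment cell (0.051), MHC class I (0.0607), interferon-gamma (0.0773), G1/S (0.235), G2/M (0.165), respiratory chain (0.245) and ribosomal protein genes (0.165), and in endothelial-labelled libraries type I interferon (0.0692), G2/M (0.0747) and mitochondrial mRNA genes (0.146), with the adjusted p by fry in brackets. For fibroblast against endothelial they were G2/M (0.125), G1/S (0.0971), MAPK output (0.346) and NRF2 targets (0.0971), for melanocyte against fibroblast G2/M (0.0959) and for melanocyte against endothelial mitochondrial mRNA (0.179). Matrix and protease lists in A375 were at 0.0739 and 0.0895 with the block, and with no filter matrix was at 0.156 and ribosomal protein genes in endothelial-labelled libraries at 0.0647. Without the libraries apart from their group interferon-gamma, G1/S and p53 lists in melanocyte-labelled libraries were at 0.219, 0.273 and 0.0581, and MHC class II and interferon-gamma in fibroblast-labelled ones at 0.111 and 0.222.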

Other observations

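Tests of explanations below were chosen after the results were seen, except the counts over other splits of the libraries. Among gene groups not yet described, inflammatory genes moved both ways in the recipients. In the fibroblast-labelled libraries 8 of 30 NF-kB and cytokine genes rose and 8 fell (19 adjusted over the list alone, camera adjusted p = 0.823), with the early response gene IER3 at 1.69 (SE 0.14) and the cytokine IL24 at -1.24 (SE 0.12). In the melanocyte-labelled libraries 2 rose and 5 of 30 fell (15 adjusted over the list alone, camera adjusted p = 0.0871), with IL1B from 384 to 184 CPM. In the endothelial-labelled libraries 8 of 30 rose and 8 fell (17 adjusted over the list alone, camera adjusted p = 0.887), with the prostaglandin synthase PTGS2 at -1.30 (SE 0.09). Of angiogenesis genes 11 of 21 rose and 7 fell in endothelial-labelled (18 adjusted over the list alone, camera adjusted p = 0.192) and 6 of 20 rose and 3 fell in fibroblast-labelled libraries (11 adjusted over the list alone, camera adjusted p = 0.0659). The latter p was 0.0394 without PRAME +/+ replicate 2 and 0.00594 without PRAME +/- replicate 3. Matrix proteases rose in 10 and fell in 3 of 19 in endothelial-labelled libraries (13 adjusted over the list alone, camera adjusted p = 0.05), with the stromelysin MMP3 at 2.14 (SE 0.11) and PLAU at -2.18 (SE 0.09). That p was 0.0337 without PRAME +/+ replicate 2 and 0.0202 without PRAME +/- replicate 1. In retinoic acid response 8 of 13 fell and 4 rose there (12 adjusted over the list alone, camera adjusted p = 0.296), with the retinoic acid hydroxylase CYP26B1 at -2.02 (SE 0.14) and DHRS3 at 1.18 (SE 0.07). NRF2 targets fell in 6 and rose in 2 of 12 (8 adjusted over the list alone, camera adjusted p = 0.132), with the heme oxygenase HMOX1 at 1.66 (SE 0.07) and the thioredoxin reductase TXNRD1 at -1.07 (SE 0.07). Lysosome genes fell in 8 and rose in 2 of 17 (10 adjusted over the list alone, camera adjusted p = 0.106), with the protease CTSL at -0.87 (SE 0.08). Chaperone genes fell in 5 and rose in 2 of 11 (7 adjusted over the list alone, camera adjusted p = 0.16), HSPH1 at -0.70 (SE 0.07).

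Of immunosuppressive factors 5 rose and 7 fell of 16 in A375 (12 adjusted over the list alone, camera adjusted p = 0.984). In the melanocyte-labelled libraries 3 of 15 rose and 0 fell (3 adjusted over the list alone, camera adjusted p = 0.702), with the galectin LGALS9 at 1.49 (SE 0.16). The counts were 2 and 4 of 15 in the fibroblast-labelled (6 adjusted over the list alone, camera adjusted p = 0.66) and 4 and 5 of 15 in the endothelial-labelled libraries (9 adjusted over the list alone, camera adjusted p = 0.696). Endothelial identity genes rose in 4 and fell in 1 of 15 in the endothelial-labelled libraries (5 adjusted over the list alone, camera adjusted p = 0.206), where PECAM1 was at 0.04 (SE 0.11) and did not pass. Lymphatic endothelial identity genes rose in 1 and fell in 1 of 5 (2 adjusted over the list alone, camera adjusted p = 0.887). Fibroblast identity genes rose in 3 and fell in 2 of 13 in the fibroblast-labelled libraries (7 adjusted over the list alone, camera adjusted p = 0.794), COL1A1 from 6640 to 11600 CPM. In the endothelial-labelled libraries 3 rose and 6 fell of 13 (9 adjusted over the list alone, camera adjusted p = 0.349). Leukocyte identity genes rose in 2 and fell in 1 of 6 in the fibroblast-labelled libraries (3 adjusted over the list alone, camera adjusted p = 0.695), with the endotoxin co-receptor CD14 at -1.96 (SE 0.13). Keratinocyte identity genes in A375 rose in 1 and fell in 2 of 5 (3 adjusted over the list alone, camera adjusted p = 0.838), KRT14 at -0.62 (SE 0.10), which did not pass in the fit over all 8 groups (adjusted p = 0.124).

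Transcripts restricted to A375 cells, MHC class II genes and interferon genes were higher in the melanocyte-labelled PRAME +/- group. Cross-talk between libraries was argued against by 4 abundant recipient genes. COL1A1, the highest of them relative to recipients, stood in A375 libraries at 0.0978% of the recipient mean, below the A375 share of 3.92%. COL1A2 stood there at 0.00146%, so the COL1A1 value may include expression by A375 cells. RNA of A375 cells as the whole cause of the type I interferon rise was argued against, since the A375 share accounted for a median of 2.33% of it over 25 called genes (0.0235% to 49.4%). For MHC class II the share accounted for a median of 52.8% over 6 called genes (26.1% to 72.3%), so A375 RNA may be a part of that rise and cannot be told apart from induction in the recipients. These percents take the share of the cancer-testis genes as that of every A375 transcript. SOX10 stood below that share, so the percents may be too high. Whether vesicles, carried cells or cell-free RNA brought the A375 RNA was not tested, and a response to the donor genotype stays open.

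Fibroblast transcripts were abundant in melanocyte- and endothelial-labelled libraries, and in the former cells of the fibroblast-labelled culture as the source were argued against, since the abundant COL3A1 stood at 0.141% of its fibroblast-labelled level (5120 CPM) and COL1A2 at 36.5%, although FAP reached 156%. In endothelial-labelled libraries such cells could not be excluded, since COL3A1 stood at 30.1%, COL1A1 at 65.2% and COL1A2 at 100%, with all 11 such genes between 12.6% (LUM) and 317% (THY1). An exchange of the melanocyte label with another recipient label was argued against, since 5 pigment genes summed to at most 0.642 CPM in the other recipient libraries and to 6.34 to 14.8 CPM in the melanocyte-labelled ones. For an exchange of the fibroblast and endothelial labels, PECAM1, CDH5, VWF, TIE1 and KDR summed to at most 4 CPM in fibroblast-labelled and to 24.6 to 31.9 CPM in endothelial-labelled libraries, which argues against it, although the sum reached 37.4 CPM in the melanocyte-labelled ones. Other fibroblast-like cells in these cultures, or a change of the labelled cells in culture, may remain as explanations and were not tested.

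Splits of the libraries into other groups of the same sizes gave the following. In A375 the labelled split was 1 of 10 with as many genes called, 6391 against at most 0 in the others. In the melanocyte-labelled libraries the numbers were 829 and 0, and in the fibroblast-labelled 2584 and 0. With 10 splits a share under 0.05 could not be reached in any of these. For the difference between melanocyte- and fibroblast-labelled responses 1 of 100 splits, drawn from 200, gave as many genes, 2890 against at most 1183. A random division of these libraries was therefore an unlikely source of that count. The splits take each library as an independent unit, so chance differences between cultures or preparations could not be excluded.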
